A study of Mus musculus with 6 samples.

How the data were processed

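Expression was measured on Affymetrix whole-genome mouse arrays in 6 samples of sorted dermal fibroblasts, 3 from dysplastic ears of K14-HPV16 mice (CAF) and 3 from normal ears (NDF). Per the labels' protocols, PDGFRα-positive cells were sorted by flow cytometry from ear suspensions of 15 mice per genotype, and RNA was amplified once with the WT-Ovation kit and labelled with biotin. A single round of whole transcript amplification from few cells can add array to array noise for scarce transcripts. The submitters' processing notes name GCOS and RMA, and versions are not given in the sources used here. The deposited values are on a log2 scale, as their range of 2.20 to 14.60 shows, and the upper percentiles of the arrays were nearly equal. RMA subtracts background, quantile normalises the arrays and summarises the probes of a set, so total intensity per array is lost and low values are compressed towards a floor. Differences of dim genes are therefore understated, and a fold against a group near the floor is a value on this scale, not a ratio of transcripts. Scanner files and detection calls were not used here, so no bound from background was set.

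The table holds 45101 probe sets, of which 64 are controls. Gene names came from the platform annotation. Of the 45037 other probe sets 34945 name 1 gene, 932 name several and 9160 are not in the annotation table, which leaves 10092 without a single name. Symbols were looked up by gene identifier in a RefSeq table of assembly GRCm38.p6, where 34741 probe sets matched and 0 symbols were updated. The genome build behind the array files is not given in the sources used here, so no coordinates are printed. For each gene the probe set with the highest mean over all 6 arrays was used, which gave 18193 genes. No sample columns were left out, and no filter on dim probe sets was applied in the main analysis.

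CAF and NDF were compared with limma 3.58.1 (lmFit and eBayes with a constant prior variance, two-sided) in R 4.3.3, on the 6 arrays with group as the only term. Adjusted p values are Benjamini-Hochberg values over all genes, with a threshold of 0.05, and standard errors are the moderated ones. The prior had 2.79 degrees of freedom and the median standard error of a difference was 0.25. Gene lists for inflammation, matrix, signalling, metabolism and cell types were written from textbook knowledge, except the study's inflammatory list, which was recalled from the study and had been chosen on these samples. Of the lists, 38 had at least 5 measured members. They were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists, with camera at an estimated correlation and fry beside it. Lists of ribosomal, loading control and sex-linked genes were only described. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

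The gene lists, the tests and the rule for named genes were fixed before the data were examined. The rule took the 12 genes with the largest differences in each direction among those past the threshold, with no overlap between the groups, a mean of the higher group at or above the median probe set (4.84) and a symbol that is not a clone or predicted gene. Where fewer than 5 genes passed in a direction, the 8 with the smallest p were taken as values. The rule added every member of the study's list, the sort marker Pdgfra, up to 3 members of each other list with the smallest p, and members of the quality and label lists. Krt14, Cma1, Mcpt4 and the predicted gene Gm19935, with genes of families named in the closing section, fall outside it and were chosen after their values were seen.

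The procedure was tested on simulated data with 18193 genes, 200 of them changed, 50 of each size. It recovered 18% of the genes changed by 1 log2 unit, 82% of those changed by 2, 82% of those changed by 3 and 96% of those changed by 4, with 10 false calls and 0 calls of the wrong sign. Of 38 lists, 1 was called without any shift. The simulated genes were drawn independently, with equal noise on all arrays. In the real data the members of a list were correlated, at an estimated 0.47 for keratinocyte genes, and the arrays differed in quality. These rates therefore need not hold for the real arrays.

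The alternatives were a replicate block, quantile normalisation again, cyclic loess, equal array medians, filters at the median and at the 25th percentile of probe set means, the mean of all probe sets of a gene, and leaving out probe sets with cross-matching suffixes. Every probe set tested on its own, an intensity trend, a robust prior, array quality weights, adjusted p under 0.1, a 2-fold minimum, other set tests and leaving out each array were also tried. After seeing the data, leaving out CAF replicate 3 and NDF replicate 1 together, and counting called genes outside the marker lists of other cell types, were added.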

Results

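Gene expression was measured in dermal fibroblasts sorted from the ears of mice 4 months old. Cancer-associated fibroblasts (CAF) came from visibly dysplastic ears of K14-HPV16 mice, a transgenic line that expresses human papillomavirus genes in basal keratinocytes and passes through premalignant skin stages. Normal dermal fibroblasts (NDF) came from the ears of non-transgenic mice of the FVB/n strain. Cells were sorted for PDGFRα, a surface receptor carried by fibroblasts. Each group had 3 arrays, which the labels call biological repetitions, and the protocol names 15 mice per genotype. It does not say whether each repetition was a separate pool, so the p-values measure the spread between these 3 samples per group. The array values were log2 intensities, with a median of 4.73 to 4.87 per array, and 18193 genes had a probe set that names 1 gene. The number of arrays limits the precision. The question behind the comparison, as the series title puts it, is whether fibroblasts of early neoplastic skin switch on genes of inflammation that depend on the transcription factor NF-κB.

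Sorted fibroblast samples from dysplastic skin had higher levels of inflammatory genes than those from normal skin, and few genes passed the threshold as lower. The chemokine Cxcl2, which attracts neutrophils, rose from 3.79 ± 0.16 in NDF to 11.61 ± 0.51 in CAF (log2, SD, n = 3), a difference of 7.82 ± 0.28 (SE) or 226-fold. The cytokine Il6 rose by 5.77 ± 0.23, from 2.74 ± 0.26 to 8.50 ± 0.28. Lcn2, which encodes an iron-siderophore binding protein of innate immunity, rose by 5.37 ± 0.23, and the wound keratin Krt6b by 6.60 ± 0.28. The limma adjusted p was 0.000281 for Cxcl2, 0.000382 for Il6 and 0.00039 for both Lcn2 and Krt6b. The angiotensin receptor gene Agtr2 fell by 3.66, from 7.89 ± 0.42 to 4.24 ± 0.78 (adjusted p = 0.0252). At an adjusted p under 0.05, 94 of 18193 genes differed, 89 higher and 5 lower in CAF. The smallest difference among them was 1.31 log2 units in size, and the median of the higher genes was 3.31. Below the threshold the directions were more even, with 897 genes higher and 732 lower at an unadjusted p under 0.05. The CAF and NDF arrays did not overlap for 15.4% of all genes, where chance gives 10%, with all CAF arrays above for 6.78% and below for 8.66%. The count fell to 11, 8 or 5 genes without NDF replicate 1, 2 or 3, and to 40 without CAF replicate 2, and was 156 without CAF replicate 3. Cxcl1, Cxcl2, Il6, Krt6b and Lcn2, the 5 left without NDF replicate 3, passed the threshold whichever array was left out.

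Among the 12 leading higher genes, several encode products of leukocytes or of the wounded epidermis. The myeloid lectin Clec4d rose by 6.47 ± 0.51 (adjusted p = 0.00982) and the neutrophil calcium-binding protein gene S100a8 by 6.04 ± 0.74 (adjusted p = 0.0304). S100a8 varied among the normal samples, at 6.15 ± 1.56, and reached 12.18 ± 0.47 in CAF. The cornified envelope gene Sprr1b rose by 6.13 ± 0.61 (adjusted p = 0.0186) and the keratin Krt6a by 5.05 ± 0.42 (adjusted p = 0.00998), with a median of 3.28 for its 2 other probe sets. The acute phase gene Saa3 rose from 4.56 ± 0.07 to 9.46 ± 0.71 (adjusted p = 0.00648). The lymphocyte activation antigen Cd69 rose from 3.07 ± 0.62 to 8.39 ± 0.91 (adjusted p = 0.0186). Il1b and Cxcl5 complete the 12 and are described with the inflammatory list. Marker genes of other cell types were also higher on the CAF arrays. Of the 94 genes, 13 belonged to a marker list of another cell type, and 81 did not, of which 76 were higher in CAF. These marker lists hold only 214 of the 18193 genes. The 81 include leukocyte genes such as Cd69 and Clec7a, so they are not all fibroblast genes.

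Too few lower genes met the criteria for a list by size, so the 8 with the smallest p are given as values. The GABA receptor subunit gene Gabra4 was at 6.08 ± 0.07 in NDF and 4.19 ± 0.24 in CAF (adjusted p = 0.0186), although its other probe set differed by only -0.07. The adhesion receptor gene Adgrg6 was at 10.84 ± 0.19 and 8.97 ± 0.41 (adjusted p = 0.0414), and the neural adhesion gene Ntm at 6.65 ± 0.11 and 5.31 ± 0.09 (adjusted p = 0.0333). With the mean of all probe sets of a gene the adjusted p was 0.0606 for Gabra4 and 0.0565 for Ntm, and for Ntm it was 0.0546 with cyclic loess and 0.0761 with an intensity trend. The 2 other probe sets of Ntm had a median of -0.83. Slc16a9, Rflna, Itm2a and Gria1 missed the threshold, with differences of -1.68, -1.43, -2.19 and -1.79 and adjusted p values of 0.0503, 0.0543, 0.0548 and 0.0622. The predicted gene Gm19935, named after its value was seen, completes the 5 lower genes at -1.70 (adjusted p = 0.0252). None of the 5 lower genes passed the threshold when any 1 NDF array or CAF replicate 2 was left out.

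The inflammatory signature of the study comprises secreted mediators and their enzymes, and 7 of its 8 members were measured. All 7 had higher values in every CAF array than in any NDF array, and 6 passed the test over all genes. Cxcl1, another neutrophil chemokine, rose from 7.10 ± 0.04 to 11.93 ± 0.17, a difference of 4.83 ± 0.17 (adjusted p = 0.000281). Cxcl5 rose by 5.24 ± 0.44 (adjusted p = 0.00998) and Il1b, the gene of interleukin 1β, by 5.56 ± 0.56 (adjusted p = 0.0186). Ptgs2, which encodes the inducible cyclooxygenase, rose from 7.90 ± 0.78 to 12.11 ± 0.16 (adjusted p = 0.0149), and its other probe set differed by 2.39. The matrix-associated protein gene Ccn1 was already high in NDF, at 11.80 ± 0.07, and was at 12.78 ± 0.06 in CAF (adjusted p = 0.0705). Without probe sets that cross-match other transcripts its difference was 2.26 (adjusted p = 0.0174). Adjusted over the list alone, all 7 passed. The median difference was 5.24, with a limma camera adjusted p of 1.11e-24, and adjusted p = 0.0363 with an estimated correlation. The study chose this list on these samples, so neither count is independent evidence of its direction. The count over all genes was 4 without NDF replicate 1 or 2, 3 without NDF replicate 3, and 6 without CAF replicate 3. On the same arrays the neutrophil marker list had a median difference of 2.93 and the macrophage and dendritic cell list 2.37.

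**Figure D1:**
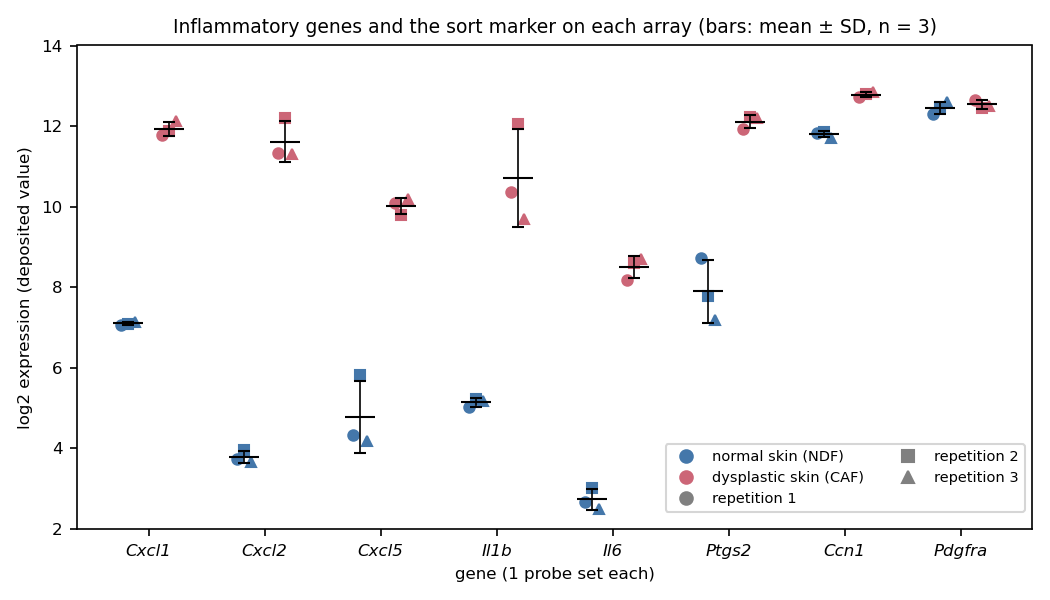
Log2 expression (vertical axis) of the 7 measured genes of the inflammatory signature and of the sort marker Pdgfra on each of the 6 arrays. Points are arrays, marked by group and repetition, and bars are the mean and SD of 3 arrays. Cxcl2 lies at 3.79 in NDF and 11.61 in CAF, whereas Pdgfra lies at 12.46 and 12.54.

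The sort marker Pdgfra had nearly equal values in both groups. Its mean was 12.46 ± 0.15 in NDF and 12.54 ± 0.11 in CAF, a difference of 0.08 with a 95% interval of -0.34 to 0.50 (adjusted p = 0.957). Of 25 measured dermal fibroblast identity genes none passed the test by limma, and 1 was higher and 1 lower at an unadjusted p under 0.05. Their median difference was -0.20 (camera adjusted p = 0.302). Col1a2, a chain of type I collagen, was at 13.72 ± 0.02 in NDF and 13.20 ± 0.17 in CAF (adjusted p = 0.402), and its 2 other probe sets had a median difference of -0.35. Pi16, a marker of adventitial fibroblasts, was at 11.17 ± 0.30 and 12.17 ± 0.16 (adjusted p = 0.153).

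Other inflammatory gene groups were also higher in CAF by camera. Among 27 NF-κB pathway members and targets, 4 rose and none fell, 9 were higher and 1 lower adjusted over the list alone, and the median difference was 0.49 (adjusted p = 3.09e-12). The lower one was the NF-κB subunit gene Nfkb2, at -0.61 (limma adjusted p = 0.0301 over the list alone). The other measured subunit genes Rel, Rela and Relb differed by 0.97, -0.40 and 0.22 and passed by neither adjustment. Besides Lcn2 and Saa3, the early response gene Ier3 rose from 10.28 ± 0.15 to 12.03 ± 0.24 (adjusted p = 0.0252). Of 19 chemokines outside the study list, 2 rose, 8 adjusted over the list alone, with a median of 1.12 (adjusted p = 6.76e-11). They were Ccl3, a macrophage inflammatory protein, at 3.92 ± 0.39 (adjusted p = 0.0186), and Cxcl3 at 4.58 ± 0.63 (adjusted p = 0.0444, and 0.0546 with cyclic loess). Of 27 cytokines and receptors outside the study list, 4 rose over all genes. Adjusted over the list alone 9 were higher and 1 lower, with a median of 0.50 (adjusted p = 2.11e-09). Il1rn, the interleukin 1 receptor antagonist, rose from 4.76 ± 0.24 to 9.47 ± 0.68 (adjusted p = 0.00794), with a median of 1.58 for its 2 other probe sets. Tnfsf11, the osteoclast factor RANKL, rose by 2.82 ± 0.35 (adjusted p = 0.0304), although its other probe set differed by 0.29. Lif rose by 2.05 ± 0.27 (adjusted p = 0.037), while its other probe set differed by -0.13 and its call was lost on quantile normalisation, cyclic loess and the mean of its probe sets (adjusted p = 0.0644, 0.0549 and 0.0694). Of 25 immediate-early genes, which also respond to tissue dissociation, 5 rose, 16 adjusted over the list alone, with a median of 0.98 (adjusted p = 9.11e-22). The antiproliferative gene Btg2 rose by 2.39 ± 0.20 (adjusted p = 0.00998), the AP-1 gene Fosb by 1.60 ± 0.16 (adjusted p = 0.0189) and the nuclear receptor Nr4a1 by 2.99 ± 0.34 (adjusted p = 0.0252). These 4 lists and the study list were the 5 that camera still called with an estimated correlation, at adjusted p = 0.0363 for NF-κB targets and cytokines, 0.0464 for chemokines and 0.0407 for immediate-early genes. On the same arrays the neutrophil and macrophage marker lists had medians of 2.93 and 2.37.

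Interferon, complement, protease and protease inhibitor genes were higher as lists by camera with a preset correlation. Of 27 interferon-stimulated genes 1 rose, 8 adjusted over the list alone, with a median of 0.64 (camera adjusted p = 6.85e-10, and adjusted p = 0.108 with an estimated correlation). It was the immunoproteasome subunit Psmb8, at 1.54 ± 0.22 (adjusted p = 0.0461), and it missed the threshold on quantile normalisation, equal array medians, the mean of its probe sets and an intensity trend (adjusted p = 0.0599, 0.0545, 0.131 and 0.0606). Its other probe set differed by 0.41. The antiviral genes Oasl2 and Rsad2 differed by 3.00 and 2.77 (adjusted p = 0.0847 and 0.115). Of 15 complement genes none passed the test by limma and 5 were higher at an unadjusted p under 0.05, 4 of them adjusted over the list alone. Their median was 0.64 (adjusted p = 1.92e-05, and adjusted p = 0.0741 with an estimated correlation). The anaphylatoxin receptor C5ar1, which myeloid cells carry, differed by 4.61 ± 0.68 (adjusted p = 0.0505), although its other probe set differed by only 0.20 and the mean of its probe sets by 2.40 (adjusted p = 0.0452). Of 25 matrix proteases 2 rose, 7 adjusted over the list alone, and the median difference was 0.19 (adjusted p = 0.006, and adjusted p = 0.278 with an estimated correlation). Stromelysin Mmp3 rose from 10.57 ± 0.23 to 12.44 ± 0.21 (adjusted p = 0.0245) and the macrophage elastase Mmp12 from 3.07 ± 0.27 to 6.59 ± 0.75 (adjusted p = 0.0234). The list of proteases lost its call without NDF replicate 2, CAF replicate 1 or CAF replicate 2 (adjusted p = 0.0523, 0.129 and 0.0515). Without NDF replicate 1 or CAF replicate 1 its median was -0.01 or -0.12. Of 12 protease inhibitors 2 rose, and 5 were higher and 1 lower adjusted over the list alone. Their median was 0.73 (adjusted p = 0.00304, and adjusted p = 0.108 with an estimated correlation). They were Slpi, an inhibitor of neutrophil elastase, at 3.17 ± 0.37 (adjusted p = 0.0252), and Serpina3n at 1.49 ± 0.20 (adjusted p = 0.0404). On the same arrays the neutrophil and macrophage marker lists had medians of 2.93 and 2.37, and the complement and protease lists hold genes of myeloid cells.

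Antioxidant, hypoxia and prostaglandin pathway genes were higher as lists by camera with a preset correlation. Of 17 antioxidant genes none passed the test by limma, 4 were higher at an unadjusted p under 0.05 and 2 adjusted over the list alone. Their median was 0.17 (camera adjusted p = 0.00151, and adjusted p = 0.109 with an estimated correlation). The metal-binding protein genes Mt1 and Mt2 differed by 1.51 and 2.06 (adjusted p = 0.0548 and 0.0864). Of 20 hypoxia and glycolysis genes none passed, none adjusted over the list alone, and 4 were higher at an unadjusted p under 0.05. Their median was 0.21 (adjusted p = 0.0024, and adjusted p = 0.123 with an estimated correlation). The oxygen sensor gene Egln3 was at 5.96 ± 0.16 in NDF and 6.88 ± 0.29 in CAF (adjusted p = 0.181), and its other probe set differed by 0.34. The prostaglandin list leaves out Ptgs2, which is in the study list and passed the test over all genes. Of its 14 measured genes none passed by either adjustment, and 1 was higher at an unadjusted p under 0.05. Their median was 0.27 (adjusted p = 0.0443, and adjusted p = 0.278 with an estimated correlation). That call was lost without NDF replicate 1 or 2 (adjusted p = 0.147 and 0.0604) and without CAF replicate 1 or 2 (adjusted p = 0.313 and 0.0598). The neutrophil and macrophage medians of 2.93 and 2.37 apply to these arrays too.

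**Figure D2:**
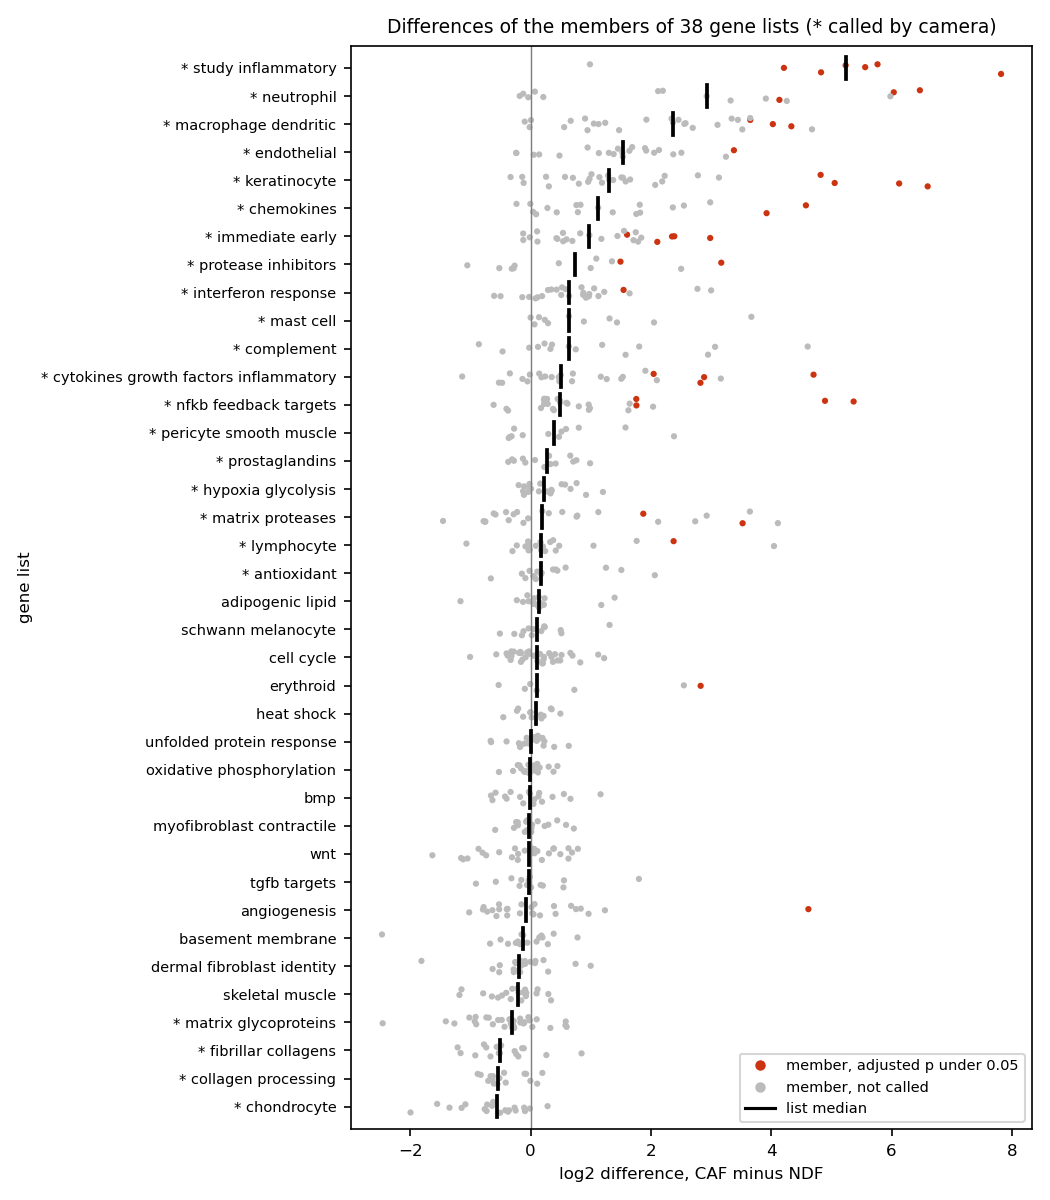
Log2 difference between CAF and NDF (horizontal axis) for every measured member of the 38 tested gene lists (vertical axis, ordered by median). Red points are members with an adjusted p under 0.05, grey points are members that were not called, black bars are list medians and asterisks mark the lists called by camera with preset correlation. The study list has a median of 5.24 and the cartilage list of -0.56.

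Markers of cells other than fibroblasts were higher on the CAF arrays. Of 29 keratinocyte genes 4 rose and 17 did adjusted over the list alone. Their median was 1.31 (camera adjusted p = 2.81e-21, and adjusted p = 0.109 with an estimated correlation). The stress keratin Krt16 rose by 4.82 ± 0.44 (adjusted p = 0.0148), beside Krt6a, Krt6b and Sprr1b, whereas the basal keratin Krt14 was at 9.39 in NDF and 11.58 in CAF (adjusted p = 0.115). Of 27 macrophage and dendritic cell genes 3 rose, 18 adjusted over the list alone, with a median of 2.37 (adjusted p = 2.75e-23, and adjusted p = 0.0943 with an estimated correlation). They were the signalling adaptor Tyrobp, the pan-leukocyte gene Ptprc (CD45) and the endotoxin co-receptor Cd14, at 3.65 ± 0.32, 4.33 ± 0.45 and 4.03 ± 0.45 (adjusted p = 0.0134, 0.0197 and 0.0252). With the mean of its probe sets Ptprc differed by 2.61 (adjusted p = 0.0549), and its other probe set by 0.89. Of 15 neutrophil genes 3 rose, 10 adjusted over the list alone, with a median of 2.93 (adjusted p = 6.93e-13, and adjusted p = 0.0753 with an estimated correlation). The third beside Clec4d and S100a8 was the receptor Trem1, at 4.14 ± 0.51 (adjusted p = 0.0304, other probe set 2.16). Of 22 endothelial genes 1 rose, 16 adjusted over the list alone, with a median of 1.53 (adjusted p = 2.89e-18, and adjusted p = 0.103 with an estimated correlation). It was the lymphatic receptor Lyve1, at 3.38 ± 0.36 (adjusted p = 0.0218), and the vascular receptor Flt1 differed by 2.37 (adjusted p = 0.0518), with a median of 1.16 for its 3 other probe sets.

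Smaller medians were seen for other marker lists. Of 21 lymphocyte genes 1 rose, 3 adjusted over the list alone, with a median of 0.17 (camera adjusted p = 0.0024, and adjusted p = 0.237 with an estimated correlation). It was the T cell receptor component Cd3g, at 2.38 ± 0.33 (adjusted p = 0.0461, and 0.0715 on quantile normalisation). Of 11 mast cell genes none passed by limma, 5 were higher at an unadjusted p under 0.05 and 3 adjusted over the list alone. Their median was 0.64 (adjusted p = 1.86e-05, and adjusted p = 0.137 with an estimated correlation). The histamine-forming enzyme Hdc differed by 3.67 (adjusted p = 0.187), and the mast cell proteases Cma1 and Mcpt4 by 0.07 and 0.00. Of 12 pericyte and smooth muscle genes none passed, 3 were higher at an unadjusted p under 0.05 and 2 adjusted over the list alone. Their median was 0.38 (adjusted p = 0.0139, and adjusted p = 0.137 with an estimated correlation). The pericyte gene Rgs5 differed by 1.58 (adjusted p = 0.176). Without CAF replicate 3 and NDF replicate 1 together the lymphocyte and pericyte lists lost their calls (adjusted p = 0.0753 and 0.0785). In that setting the female transcript Xist, described below, also separated the groups. Of 7 red cell genes 1 rose, the haem synthesis enzyme Alas2 at 2.83 ± 0.41 (adjusted p = 0.0496), and the list was not called (median 0.10, adjusted p = 0.067). The list was called without NDF replicate 1 or CAF replicate 3 (adjusted p = 0.024 and 0.0422). Alas2 lost its call on quantile normalisation, cyclic loess and a robust prior (adjusted p = 0.0674, 0.059 and 0.0537).

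**Figure D3:**
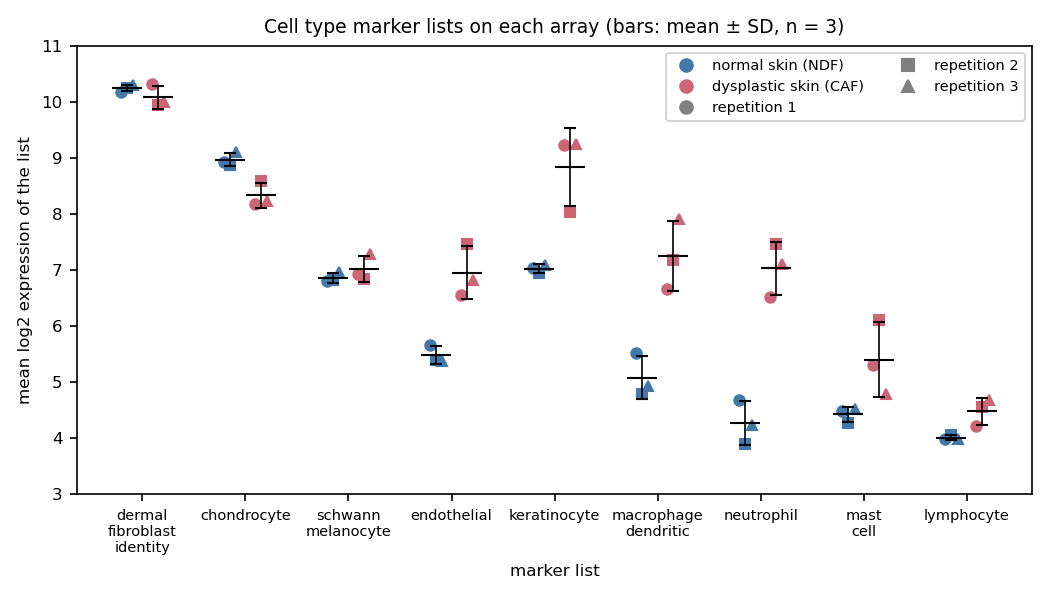
Mean log2 expression of 9 cell type marker lists (horizontal axis) on each of the 6 arrays. Points are arrays, marked by group and repetition, and bars are the mean and SD of 3 arrays. The keratinocyte list was at 9.23, 8.04 and 9.24 on the CAF arrays and at 6.94 to 7.09 on the NDF arrays.

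Collagen, matrix and cartilage genes were lower on the CAF arrays as groups, and no single member passed the limma test over all genes. Of 18 interstitial collagens 8 were lower at an unadjusted p under 0.05 and 1 adjusted over the list alone. Their median was -0.52 (camera adjusted p = 4.22e-06, and adjusted p = 0.109 with an estimated correlation). Col5a2 was at 12.54 ± 0.05 in NDF and 11.77 ± 0.05 in CAF (adjusted p = 0.128), and Col5a1 at 11.58 ± 0.43 and 10.37 ± 0.44 (adjusted p = 0.235). Of 16 collagen-modifying enzymes 6 were lower at an unadjusted p under 0.05 and none adjusted over the list alone. Their median was -0.53 (adjusted p = 8.03e-05, and adjusted p = 0.15 with an estimated correlation). The lysyl hydroxylase Plod1 differed by -0.88 and the collagen chaperone Serpinh1 by -0.63 (adjusted p = 0.216 and 0.322), and the other probe set of Plod1 by only -0.07. Of 33 matrix glycoproteins 8 were lower at an unadjusted p under 0.05 and 3 adjusted over the list alone. Their median was -0.31 (adjusted p = 5.33e-05, and adjusted p = 0.278 with an estimated correlation). Without CAF replicate 3 and NDF replicate 1 together, an alternative chosen after seeing the data, the glycoprotein median was -0.16 and the call was lost (adjusted p = 0.0821). Xist also separated the groups in that alternative. Cthrc1, a secreted protein of matrix repair, was at 9.24 ± 0.47 in NDF and 6.78 ± 0.66 in CAF (adjusted p = 0.0633), and elastin (Eln) at 11.41 ± 0.32 and 10.15 ± 0.26 (adjusted p = 0.108). Of 20 cartilage genes 8 were lower at an unadjusted p under 0.05 and 4 adjusted over the list alone. Their median was -0.56 (adjusted p = 2.43e-07, and adjusted p = 0.109 with an estimated correlation). The chondrocyte genes Cnmd and Col9a1 were at 10.52 ± 0.18 and 12.10 ± 0.21 in NDF and at 8.52 ± 0.60 and 10.54 ± 0.58 in CAF (adjusted p = 0.0633 and 0.128). On the same arrays the keratinocyte, neutrophil and endothelial marker lists had medians of 1.31, 2.93 and 1.53.

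Lists for myofibroblast contraction and growth factor signalling were not called by camera. Of 21 myofibroblast genes none passed by limma and 1 was higher at an unadjusted p under 0.05 (median -0.03, mean 0.03, camera adjusted p = 0.725). The list called TGF-β here mixes targets of TGF-β and of the regulators YAP/TEAD. Of its 15 genes none passed, 2 were higher and 1 lower at an unadjusted p under 0.05 and 1 was higher adjusted over the list alone (median -0.03, mean 0.07, adjusted p = 0.757). The activin subunit gene Inhba was at 5.95 ± 0.36 in NDF and 7.75 ± 0.47 in CAF (adjusted p = 0.0802), although its other probe set differed by -0.27. Of 26 angiogenic factors 1 rose, the EGF family ligand Ereg, from 4.84 ± 0.58 to 9.46 ± 0.82 (adjusted p = 0.0186), and the list was not called (median -0.07, mean 0.12, adjusted p = 0.979). The Wnt list had a median of -0.03 (adjusted p = 0.636), the BMP list of -0.01 (adjusted p = 0.979) and the basement membrane list of -0.12 (adjusted p = 0.807). No member of these 3 passed by limma, and at an unadjusted p under 0.05 the Wnt list had 2 higher and 5 lower, the BMP list 1 higher and the basement membrane list 1 higher and 1 lower. Of 39 proliferation genes none passed by limma and 1 was higher at an unadjusted p under 0.05 (median 0.11, adjusted p = 0.221). The proliferation list was called higher without NDF replicate 1 (median 0.34, adjusted p = 7.45e-06), and so was the myofibroblast list (median 0.13, adjusted p = 0.00705). NDF replicate 1 had a proliferation list mean of 6.98, against 5.77 and 6.14 on the other NDF arrays. Heat shock genes had a median of 0.09 (adjusted p = 0.254), respiratory chain genes of -0.0036 (mean 0.0045, adjusted p = 0.725) and endoplasmic reticulum stress genes of 0.01 (mean -0.01, adjusted p = 0.757), with 0 members past limma's adjusted threshold and 0 at an unadjusted p under 0.05. The median lay below 0 and the mean and the direction of the test above it for the myofibroblast, TGF-β, angiogenic and respiratory chain lists, and the mean alone lay below 0 for endoplasmic reticulum stress genes. Adipocyte, Schwann cell and melanocyte, and skeletal muscle lists had medians of 0.13, 0.11 and -0.21 (adjusted p = 0.174, 0.315 and 0.081). None of their members passed by limma, and 1, 1 and 0 were higher at an unadjusted p under 0.05. The muscle list was called lower without NDF replicate 1 or 3 (adjusted p = 0.00705 and 0.00851).

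Camera called 23 of the 38 lists with a preset correlation, 19 higher and 4 lower in CAF. With an estimated correlation it called 5, and fry, which tests whether the genes of a list move one way on balance, called 15. The array labelled CAF replicate 3 stood apart from the other 5. Its mean correlation with them across genes was 0.921, against 0.956 to 0.968 for the others, and it set the first principal component, which held 54.4% of the variance. Without it camera called 24 lists, including all 23. Means of 24 ribosomal protein genes were 10.92 in NDF and 10.91 in CAF, and means of 11 loading control genes were 11.08 in both groups. The 3′ minus 5′ signal of the actin control was 1.39 to 1.68 on NDF arrays and 1.30 to 1.72 on CAF arrays. The 18S ribosomal RNA control was at 12.96 to 13.29 on NDF arrays and lower on each CAF array, at 12.35 to 12.94, and the BioB spike was highest on CAF replicate 3, at 11.70 against 10.54 to 11.21. These controls were not tested between the groups.

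The labels call all 6 samples male. The Y-linked gene Eif2s3y was at 10.21, 10.76 and 10.49 on NDF replicates 1, 2 and 3, and at 10.97, 11.21 and 9.89 on CAF replicates 1, 2 and 3. The female X inactivation transcript Xist was at 10.39, 4.00 and 3.71 on the NDF replicates and at 9.09, 10.70 and 4.64 on the CAF replicates, in the same order. A high Xist signal with a high Y-linked signal is thus present on NDF replicate 1 and CAF replicates 1 and 2. With NDF replicate 1 and CAF replicate 3 left out together, the high Xist signal remains on CAF arrays only. That setting is therefore confounded with Xist.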

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

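Of the 10092 probe sets that name no gene or several, which the comparison by gene leaves out, 8 were higher and 1 was lower in the CAF arrays than in the control NDF arrays. They were tested by limma among all 45037 probe sets that are not controls, and this test was chosen after the data had been seen. The probe set 1417714_x_at had the largest difference, 3.51 (adjusted p = 0.0454), with all 3 CAF arrays above all 3 NDF arrays. The lower one, 1448194_a_at, differed by -2.23 (adjusted p = 0.0425) and was high in NDF, at 13.12, 12.40 and 12.84, against 10.61, 10.35 and 10.71 in CAF. No explanation was tested for either.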

How the results depend on the processing

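The direction of the main results was stable to further normalisation of the deposited values. The number of genes called was not stable to the arrays or to the variance model. The count of 94 genes was 71 to 125 under the 3 other normalisations, both filters, other probe set choices, the robust prior and the 2-fold minimum. It was 155 with an intensity trend (135 higher, 20 lower, 90 of the 94 kept), 438 with array quality weights (343 higher, 95 lower, all 94 kept) and 198 at an adjusted p under 0.1, and 5 to 156 when 1 array was left out. Of the 94, 83 were kept among the 156 called without CAF replicate 3, and 58 among the 113 called without that array and NDF replicate 1, chosen after seeing the data. In that last setting Xist was high on every CAF array kept and low on every NDF array kept (difference 6.04, limma adjusted p = 0.021). Group and the Xist signal therefore cannot be told apart in it. Array quality weights gave CAF replicate 3 a weight of 0.167, against 0.818 to 2.56 for the others. Leaving out an array leaves fewer samples, and for the other shifts the cause was not tested. The 6 called members of the study's list became 3 to 6 with 1 array left out and 6 or 7 under the settings other than the replicate block. The 23 called lists became 5 with an estimated correlation and 15 by fry, and 21 to 26 with 1 array left out and under the other settings. Over the single genes and list medians of all settings, 2289 and 728 values kept their direction and their side of the threshold, 127 and 16 newly passed it, 189 and 44 no longer did, and 3 and 47 changed sign. The median of all genes lay at -0.04 and moved by less than 0.1 under each scaling, from -0.05 to 0.00. Array signal is compressed near the floor, which limits differences of dim genes.

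The replicate numbers showed no clear pairing of the samples. The check used deviations from the mean of 3 arrays per group, which constrain each other, so it cannot exclude a pairing. Deviations of samples with the same number correlated at -0.153, 0.108 and -0.0132, and not every sample correlated best with its own number. With the replicate number as a block, 20 genes (all among the 94), 3 study members and 22 lists were called.

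Signs changed mostly for small differences, nearly all without a call, and the cause was not tested. An exception in size was Car3, at -1.17 in the main analysis (adjusted p = 0.85). With CAF replicate 3 and NDF replicate 1 left out, Des was at -0.034 and the medians were 0.159 for myofibroblast genes (adjusted p = 0.0044), 0.0266 for respiratory chain, -0.0063 for endoplasmic reticulum stress, -0.0903 for adipocyte and -0.178 for Schwann cell and melanocyte genes. With array quality weights, Car3 was at 0.101, and the medians were 0.069 for myofibroblast, 0.0377 for TGF-β, 0.0562 for BMP, 0.102 for respiratory chain (adjusted p = 0.0301), -0.0157 for adipocyte and -0.0286 for Schwann cell and melanocyte genes. With cyclic loess they were 0.0282 for myofibroblast, 0.0386 for TGF-β, 0.0272 for Wnt, 0.0701 for BMP and 0.0941 for respiratory chain genes. Quantile normalisation gave 0.0216 for BMP and 0.0042 for respiratory chain genes, and equal array medians gave -0.0056 for endoplasmic reticulum stress genes. The filter at the median probe set gave -0.0406 for matrix proteases, which lost their call (adjusted p = 0.0885), 0.015 for angiogenic and -0.0754 for Schwann cell and melanocyte genes. The mean of all probe sets gave 0.0466 for BMP and -0.0411 for endoplasmic reticulum stress genes. Without cross-matching probe sets, respiratory chain genes were at 0.0058 and endoplasmic reticulum stress genes at -0.0263. With 1 array left out, medians ranged from -0.173 to 0.0024 for basement membrane, -0.121 to 0.424 for matrix proteases, -0.101 to 0.126 for myofibroblast, -0.0601 to 0.0675 for TGF-β and -0.135 to 0.0939 for BMP genes. They ranged from -0.132 to 0.344 for proliferation, -0.0781 to 0.166 for respiratory chain, -0.0496 to 0.0404 for endoplasmic reticulum stress, -0.0988 to 0.261 for adipocyte and -0.137 to 0.181 for Schwann cell and melanocyte genes. The difference of Eif2s3y ranged from -0.0559 to 0.60.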

Other observations

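Gene families beyond the fixed lists were tested too, and they partly repeat those lists. They were chosen after seeing the data, and so were the tests of marker shares, wrong labels, rank correlation and myeloid RNA given here. Of the called genes in these families, Clec4d and S100a8 are also in the neutrophil list, Krt6a, Krt6b, Krt16 and Sprr1b in the keratinocyte list, Il1b and Il6 in the study's list and Il1rn in the cytokine list. By limma's camera, adjusted over 15 added families, 8 genes of colony-stimulating factors and their receptors were higher in CAF (median 1.34, adjusted p = 2.54e-07, and adjusted p = 0.05 with an estimated correlation). Csf2rb, a beta chain of the colony-stimulating factor 2 receptor, rose by 3.83 (adjusted p = 0.0186, other probe set 2.79). The 8 Fc receptor genes had a median of 1.11 (adjusted p = 1.73e-05) and none passed the test over all genes, with 5 higher at an unadjusted p under 0.05. Of 26 C-type lectins 2 rose, Clec4d and the fungal sensor Clec7a (3.65, adjusted p = 0.0304), with a family adjusted p of 0.00014. Of 73 interleukin and receptor genes 6 rose, 3 of them in a fixed list, and among the others Il7r by 4.48 (adjusted p = 0.0412, other probe set 1.98), with a family adjusted p of 6.95e-06. The medians of the lectin and interleukin families were only 0.08 and 0.16. For Fc receptors, lectins and interleukins the adjusted p = 0.0447 with an estimated correlation. The neutrophil and macrophage marker lists had medians of 2.93 and 2.37 on these arrays. The 9 small proline-rich genes had a median of 1.45 (adjusted p = 2.48e-05, and adjusted p = 0.275 with an estimated correlation), and of 0.16 without CAF replicate 3 (adjusted p = 0.00157). Keratins and S100 genes were called higher with all arrays (adjusted p = 0.0185 for both), with adjusted p = 0.543 and adjusted p = 0.19 with an estimated correlation. Their medians were only 0.02 and 0.06. Neither was called without CAF replicate 3 (medians -0.08 and 0.13, adjusted p = 0.423 and 0.062), and keratins were not called with cyclic loess (adjusted p = 0.059). None of the called families changed direction under quantile normalisation, cyclic loess or equal array medians. Solute carriers and odorant receptors were not called (adjusted p = 0.881 for both).

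Imprinted genes of growth control were lower in CAF as a family of 18, picked after the value of Mirg had been seen (median -0.67, camera adjusted p = 1.52e-06, and adjusted p = 0.0447 with an estimated correlation). Without Mirg the other 17 had a median of -0.55 (adjusted p = 1.08e-05, and adjusted p = 0.0447 with an estimated correlation). On the same arrays the keratinocyte, neutrophil, macrophage and endothelial marker lists had medians of 1.31, 2.93, 2.37 and 1.53. None of the 18 passed the limma test over all genes, and 6 were lower at an unadjusted p under 0.05, with differences of -1.19 for Cdkn1c, -1.56 for Mirg, -1.05 for Plagl1, -1.25 for Rian, -1.01 for Peg3 and -0.42 for Igf2r. The other probe sets of Mirg and Peg3 differed less, by -0.13 and by a median of -0.32. Those of Plagl1 and Rian differed more, by medians of -1.71 and -1.75, and that of Igf2r by -0.81. Without CAF replicate 3 the median was -0.46 (adjusted p = 3.86e-05). The 336 zinc finger genes named Zfp had a median of -0.19 with all arrays (adjusted p = 0.000457, and adjusted p = 0.186 with an estimated correlation) and of -0.13 without CAF replicate 3 (adjusted p = 0.0659), and 32 and then 41 of them were lower at an unadjusted p under 0.05.

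Keratinocyte, macrophage, neutrophil and endothelial markers were higher in CAF although the cells had been sorted for PDGFRα. A lower fibroblast share that raises all other types alike could not be decided. Over all members, the neutrophil list mean rose by 1.28 more than the endothelial, beyond the range within either group (at most 0.525). These lists started at different heights above the floor, at 4.3 and 5.5 in NDF, so equal shares need not give equal shifts. The cartilage list mean fell from 8.97 ± 0.11 to 8.33 ± 0.22, as the collagen and matrix lists also fell. The neutrophil and endothelial pair was picked after the shifts were seen, as the most and least shifted of the 4 lists. The first contrast tried, keratinocyte minus endothelial, used only members above the median probe set. It did not separate the groups (2.54, 0.34 and 2.37 on CAF arrays, 1.23 to 1.66 on NDF). Of 75 members above the median probe set 63, or 84%, were higher in all CAF than in all NDF arrays. The share was 8.16% among all genes above that probe set, and chance gives 5%. The cut was on the mean over all 6 arrays, and only 50 of the 93 measured members lay above it in NDF. Other cells carried through the sort and expression by the fibroblasts themselves would both give this 84% and cannot be told apart, since a bulk array does not separate cells.

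The study's inflammatory list was higher in CAF under each normalisation. At least 6 of 7 members passed under 3 other normalisations, applied on top of the deposited values. RMA had already quantile normalised these values. The authors' own step was thus not undone, and these counts cannot exclude it as a cause. RNA of myeloid cells in the sort may contribute. The list means of 10.91, 11.37 and 11.01 on the CAF arrays stood beside neutrophil list means of 6.52, 7.46 and 7.10. The macrophage list means ranked otherwise, at 6.66, 7.17 and 7.905. That relation could be tested on only 3 CAF arrays, so the source of these transcripts cannot be told apart, and a change in the fibroblasts themselves stays open. Among the 10 splits of the 6 arrays into 3 and 3, 1, the real one, gave 6 members and the highest other gave 0. The list was chosen on these samples, so this outcome was favoured in advance and is no test of chance. The 10 splits are also too few for a share under 0.05.

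CAF replicate 3 stood apart from the other 5 arrays. Quantile normalisation again, the planned test of scale, moved nothing and decides nothing, with a mean correlation of 0.921 before and after, but a change of scale is argued against because the mean rank correlation, which it cannot alter, was 0.893, against 0.939 to 0.953 on the others. Its inflammatory list mean was 11.01, against 6.18 ± 0.23 in NDF, but that list was chosen on these samples and cannot test the label. The keratinocyte and endothelial lists were written before the data were examined, but were picked for this check after they were seen to be higher in CAF. Their means were 9.24 and 6.83 on CAF replicate 3, against 7.02 ± 0.07 and 5.48 ± 0.16 in NDF. These values argue against an NDF sample under a CAF label, within the limit of that choice. Xist, at 4.64 on this array, varied within each group and cannot test the label. Loss or gain of single amplified regions is a candidate explanation, because deviations of 2 probe sets of a gene correlated at 0.365 over 4895 genes on this array and at 0.498 to 0.618 on the others. On it, 251 genes lay more than 2 log2 units below and 161 above every other array, and a biological difference of this sample stays open and untested.

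The same 10 splits were used for the other counts, where the share cannot be under 0.05. The real grouping, 1 split, gave 94 genes and the highest other gave 0. It gave 23 lists, and the highest other, which put NDF replicates 1 and 2 with CAF replicate 1, gave 16.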
